A study of Hernandia nymphaeifolia with 9 samples.

How the data were processed

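Leaf polyadenylated RNA of 2-year-old Hernandia nymphaeifolia seedlings was sequenced on DNA nanoballs, per the labels' protocols. Seedlings were submerged up to their branches for 3 h in every 12 h, in fresh water or in saline water, per the labels' protocols. The groups analysed here were the fresh water control and 300 mM NaCl at 7 d and 14 d, with 3 separate seedlings each. Further NaCl levels of 150, 500 and 700 mM named in the protocol were not analysed here. The sampling day of the control was not given in the sources used here.

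The deposited values are estimated counts per assembled transcript, not scaled between libraries. FastQC, HISAT2 and Salmon are named in the submitters' processing notes without version, role or order. The row identifiers have the form that the Trinity assembler gives to isoforms of assembled genes, per the file headers and identifiers. The settings of the assembly and its filters are not given in the sources used here. All deposited values were whole numbers, and since Salmon estimates how reads shared by isoforms are divided, they were taken as rounded estimated counts and used as deposited. Isoforms of 1 assembled gene can share reads, so a call for an isoform is less certain than one for the sum of its gene. Of the 416949 transcripts, 15271 had no count in any library. No genome, annotation or table pairing identifiers with names was used here, so the gene lists fixed in advance (ion transport, abscisic acid, osmotic adjustment and others) were not tested.

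Counts were analysed in R 4.3.3 with edgeR 4.0.16. Transcripts were kept by edgeR's expression filter (minimum count 10, minimum total 15), which left 98906. Libraries were scaled by TMM. One quasi-likelihood model with a mean per group and no other covariate was fitted to all 9 libraries, so that the 3 groups shared an estimate of the spread. The common dispersion was 0.0845, a biological coefficient of variation of 0.291. Each pair of groups and any difference among the 3 groups were tested with edgeR's quasi-likelihood test, and calls were made at a Benjamini-Hochberg adjusted p below 0.05. CPM were computed from the deposited counts with TMM-scaled library sizes, and log2 CPM with a prior count of 2. Principal components and Euclidean distances used the 500 most variable transcripts, and groups were compared with exact permutation tests. Sizes of effects were computed over transcripts with a mean of 5 CPM or more, after subtracting the spread within groups. Total counts were 13166552 to 14201943 per library. With TMM-scaled library sizes taken over the tested transcripts, 3 counts were worth 0.218 to 0.239 CPM.

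The transcripts named were, among calls at 14 d with a mean of 5 CPM or more and all 3 libraries of a group above all 3 of the other, the 2 with the largest positive and the 2 with the largest negative fitted log2 change. This rule, the designs and most alternatives were chosen before the data were examined. A fold against a group without counts was computed as a bound, against 3 counts over that group. Replicate pairs within groups differed by more than counting noise (chi-square per degree of freedom 4.39 to 13.4), so no library was treated as a duplicate.

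The test was checked on simulated counts with 100 transcripts changed at each size, all with a mean of 5 CPM or more. For 7 d against control it recovered 84% of 4-fold and 12% of 2-fold changes among 93295 transcripts. For 14 d against control it recovered 83% and 12% among 93255, and for 14 d against 7 d 87% and 9% among 93335. The overlap of calls between comparisons with the same controls was set beside simulated groups without effect. The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling, other filters on low counts, stricter thresholds, the replicate number as a block, fits of 2 groups only, counts summed per assembled gene, and each library left out in turn. Thinning of all libraries to the lowest total, the ratio of squared effects, the sums per gene for the overlap and the classes, and scaling by total counts only for the classes were added after the data were examined. Figures and further summaries were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.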

Results

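Hernandia nymphaeifolia is a tree of tropical coasts that grows at the landward edge of mangroves, and the study asked how the leaf transcriptome of its seedlings was altered by salt water. Leaf polyadenylated RNA of 9 seedlings was sequenced, 1 library per seedling. The control group of 3 seedlings was kept in fresh water, 3 seedlings received 300 mM NaCl for 7 days and 3 received 300 mM NaCl for 14 days. The sampling day of the control seedlings is not given in the labels. Total estimated counts ran from 13166552 to 14201943 per library, with a mean of 13757653. The values covered 416949 assembled transcripts of 315331 assembled genes, of which 98906 transcripts had enough counts to be tested and held 96.3 to 96.9% of the counts of each library. Of the tested transcripts, 58336 belonged to assembled genes with 2 or more tested isoforms. No names or functions came with the transcripts, so groups of transcripts are described by their direction and time course.

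The leaves of the 3 groups had different transcript profiles. On the 500 most variable transcripts, the first principal component held 47.7% of the variance and placed the control libraries at -59.4 ± 3.87 (SD, n = 3), the 7 d libraries at 43.5 ± 4.63 (SD, n = 3) and the 14 d libraries at 15.9 ± 5.79 (SD, n = 3). The 14 d libraries thus lay between the control and the 7 d libraries on this component. The second component held 19.6% of the variance and set 14 d replicates 1 and 2, at -46.6 and -47.7, apart from all other libraries, while 14 d replicate 3 lay at -10.6. Distances between groups exceeded distances within groups by a mean of 38.2 log2 units over the 3 groups, with an exact permutation p = 0.00357, the smallest that the 280 partitions allow. For each pair of groups the exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give.

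**Figure D1:**
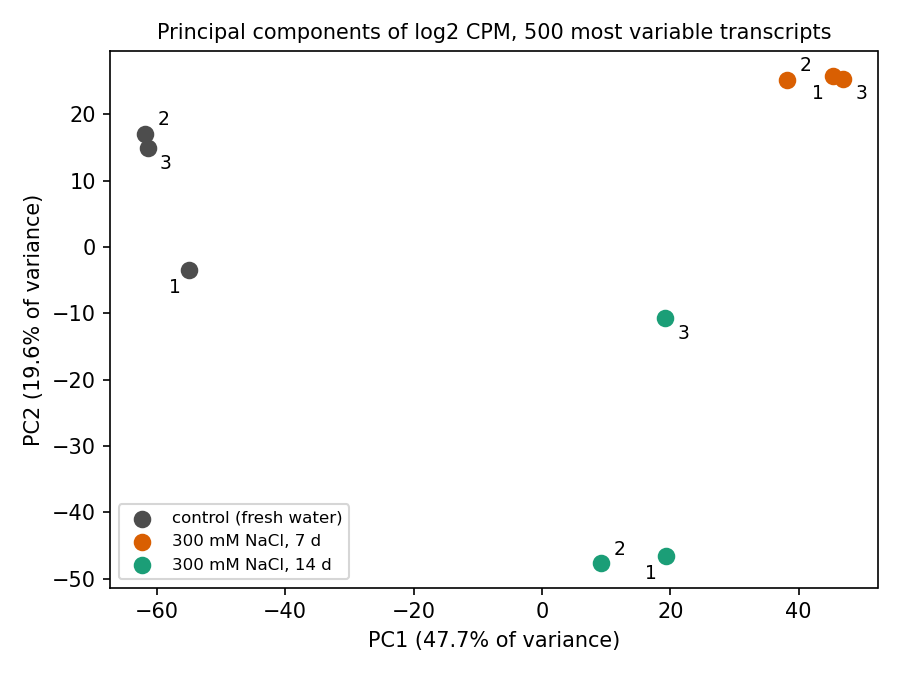
First and second principal components of log2 CPM (library-scaled counts) over the 500 most variable transcripts, 1 point per library, numbered by replicate and coloured by group. The control libraries lie at the left (mean -59.4 on the first component), the 7 d libraries at the right (43.5) and the 14 d libraries between them (15.9), with 14 d replicate 3 at -10.6 on the second component.

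The first comparison asked which leaf transcripts differed after 7 days of salt. Against control leaves, 19334 transcripts differed, of which 8861 rose and 10473 fell. The transcripts that rose made up 9.47 ± 0.504% (SD, n = 3) of the counts in control leaves and 23.8 ± 1.55% (SD, n = 3) in 7 d leaves. Those that fell went from 25.9 ± 1.37% (SD, n = 3) to 11.2 ± 0.577% (SD, n = 3). Because these transcripts were selected by the same test, the shares describe the size of the response and are not a separate test of it. The median change was 1.47 on the log2 scale among transcripts that rose and -1.48 among those that fell, and 14416 transcripts changed at least 2-fold. Abundant transcripts were called more often: 41.3% of the 3544 transcripts with a mean of 50 CPM or more, against 11.5% of the 23214 with a mean under 1 CPM. Calls were made with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and an unadjusted p under 0.05 was reached by 32426 transcripts. Leaving out 7 d replicate 3 lowered the count of changed transcripts to 12227.

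The second comparison asked the same after 14 days. Against the same control leaves, 11087 transcripts differed, of which 5566 rose and 5521 fell. Which direction held more calls depended on the method, with 6309 higher and 4721 lower when libraries were scaled by total counts only, and 4009 higher and 4987 lower with limma-voom. Transcripts that rose went from 4.97 ± 0.128% (SD, n = 3) of the counts in control leaves to 13.7 ± 0.895% (SD, n = 3) in 14 d leaves, and those that fell went from 19.1 ± 1.06% (SD, n = 3) to 9.49 ± 0.48% (SD, n = 3). These shares again describe transcripts selected by the same test. The median change was 1.67 on the log2 scale among transcripts that rose and -1.34 among those that fell, and 8360 changed at least 2-fold. An unadjusted p under 0.05 was reached by 24943 transcripts. Over 29518 transcripts with a mean of 5 CPM or more, the mean squared log2 difference from control after subtraction of the spread within groups was 0.672 at 14 d and 0.988 at 7 d, a ratio of 0.680 that lay between 0.621 and 0.747 when each library was left out in turn. The count of transcripts changed at 14 d was 6342 without 14 d replicate 1 and 7308 without control replicate 3.

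**Figure D2:**
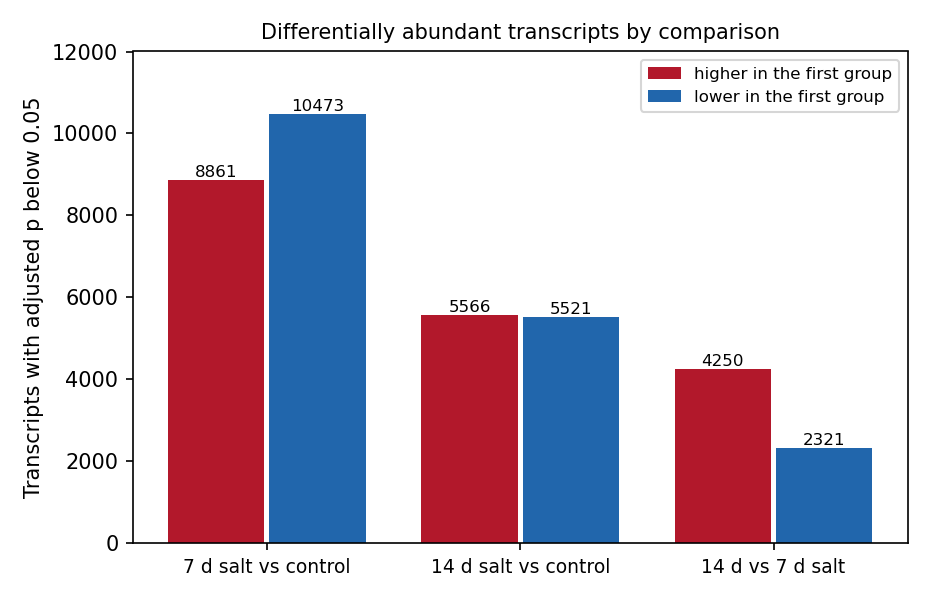
Numbers of transcripts that were higher (red) or lower (blue) in each of the 3 comparisons, counted at an adjusted p below 0.05. After 7 d of salt 8861 rose and 10473 fell against control, after 14 d 5566 rose and 5521 fell, and between 7 d and 14 d of salt 4250 rose and 2321 fell.

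The third comparison asked which transcripts differed between 14 and 7 days of salt. It found 6571, of which 4250 were higher at 14 d and 2321 lower, so that 64.7% of them were higher at 14 d. Among transcripts with a mean of 50 CPM or more the directions were nearly even, 300 higher and 314 lower. Transcripts higher at 14 d than at 7 d held 10.3 ± 0.684% (SD, n = 3) of the counts in control leaves, 4.13 ± 0.239% (SD, n = 3) in 7 d leaves and 9.6 ± 1.02% (SD, n = 3) in 14 d leaves. Transcripts lower at 14 d held 6.83 ± 0.293% (SD, n = 3) in control leaves, 10.3 ± 0.489% (SD, n = 3) in 7 d leaves and 5.53 ± 0.326% (SD, n = 3) in 14 d leaves. Here too the transcripts were selected by the same test, so the shares at 7 d and 14 d are not a separate test. An unadjusted p under 0.05 was reached by 22121 transcripts. The count of 6571 depended on single libraries: it was 3041, 3605 and 2352 without 7 d replicates 1, 2 and 3, and 3206 and 2427 without 14 d replicates 1 and 2. Without 14 d replicate 3 it was 8827. Leaving out a library also lowers the number of samples, which may account for part of the lower counts.

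The responses at both times overlapped. In total 7266 transcripts changed in the same direction at 7 d and at 14 d, 3855 upwards and 3411 downwards. Independent lists of the same lengths would share 499 and 585. Transcripts that rose at both times made up 69.3% of all that rose at 14 d, and those that fell at both times 61.8% of all that fell at 14 d. Of the longer lists at 7 d they made up 43.5% and 32.6%. Across 29518 transcripts, which are not independent replicates, the log2 differences from control at both times had a correlation of 0.743 and a covariance of 0.692. Both comparisons use the same control libraries. In simulated groups without any effect the highest overlap called by edgeR over 5 draws was 0, with a mean correlation of 0.502 and a mean covariance of 0.0522. At most 1 transcript was called at 7 d and 0 at 14 d in a draw. An overlap was thus not possible there, and the draws do not tell how much overlap shared controls add to long lists. The covariance less the part from the shared controls was 0.635. The controls were too few to be divided, so part of the excess in overlap may come from the shared controls. Without 14 d replicate 1 the overlap was 4523.

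Along the time course, each changed transcript was placed in a class only where the test between 14 d and 7 d allowed it. A sustained response, called at both times in the same direction with no call between them, was found for 6408 transcripts, 3530 higher and 2878 lower. This class rests on the lack of a call between the times, so its members may still differ between 7 d and 14 d. The sustained transcripts that rose had a median log2 change of 1.88 at 7 d and 1.77 at 14 d, and those that fell -1.45 and -1.44. A response that moved back, called at 7 d and called in the opposite direction from 7 d to 14 d without passing to the other side of control by the test at 14 d, was found for 3945 transcripts. Of these 3945, 1088 had risen at 7 d, with a median log2 change of 1.63 that was 0.18 at 14 d, and 2857 had fallen, with -1.82 and -0.19. At 14 d, 868 of the former and 2461 of the latter did not differ from control by the test. A separate class of 114 did pass to the other side. Both calls behind the class that moved back use the same 7 d libraries. Chance deviations in these may therefore enlarge both its change at 7 d and its return. A further change at 14 d was found for 1460 transcripts, 666 higher and 794 lower, of which 242 had been called in the same direction at 7 d. Another 8625 transcripts called at 7 d and 2489 called at 14 d had no call between the salt times, so their time course was not resolved. In 5 simulated draws with equal effects at both times, at most 0 transcripts were classed as moved back and 1 as further changed. At most 1 transcript per draw was called between the salt times there, and both classes need such a call. The draws therefore do not tell how many members of these classes arose by chance. Leaving out single 7 d libraries or 14 d replicates 1 or 2 moved the classes by over 1.5 times, to 1518 moved back and 570 further changed without 7 d replicate 3, 1864 and 791 without 7 d replicate 1, 2433 and 715 without 7 d replicate 2, 2147 and 652 without 14 d replicate 1, and 1643 and 541 without 14 d replicate 2. Without 14 d replicate 3, 4922 transcripts moved back and 2247 changed further, and without 14 d replicate 1 sustained transcripts numbered 4217.

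**Figure D3:**
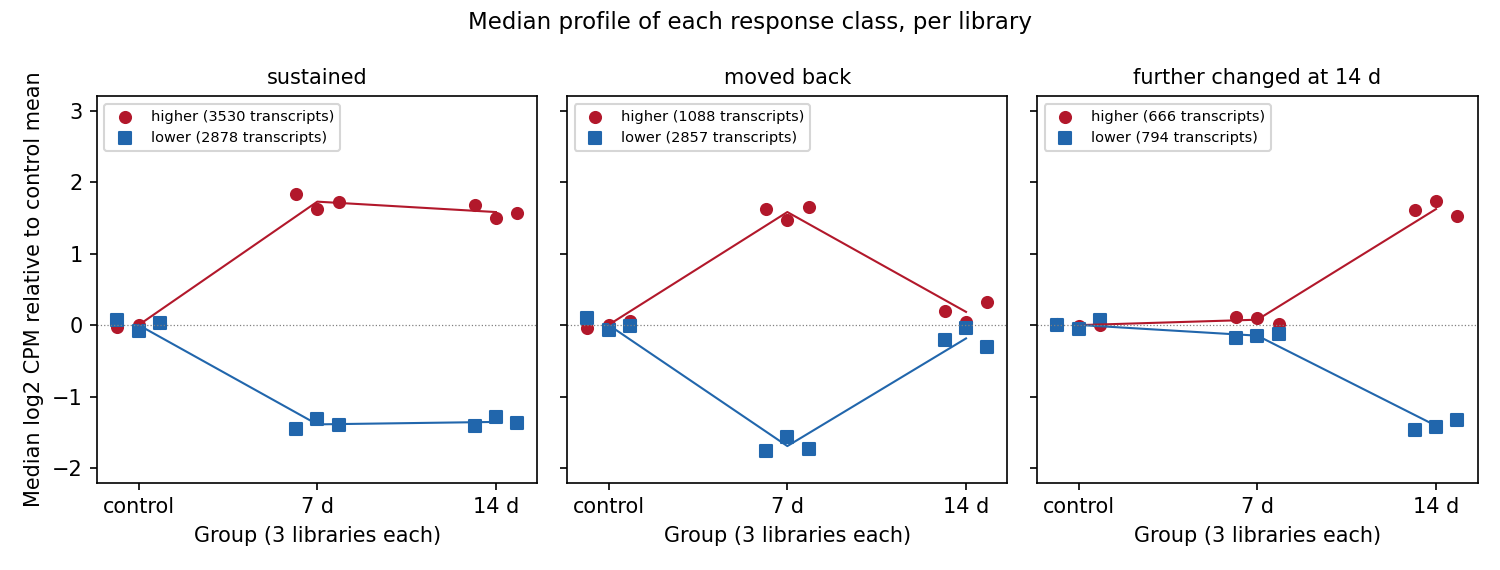
Median log2 CPM relative to the control mean of the transcripts in each response class, 1 point per library, for higher (red circles) and lower (blue squares) transcripts, with lines through the group means. The medians of sustained transcripts lie away from 0 at both times, those of the 1088 and 2857 that moved back lie near 0 at 14 d, and those of the 666 and 794 that changed further lie near 0 at 7 d, although 242 of these were also called at 7 d. The classes were set from the same libraries.

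A test of any difference among the 3 groups, made on the same 98906 transcripts, called 20379, or 20.6%. Of these, 20097 were also called in at least 1 of the 3 comparisons, which together called 24093. Without 7 d replicate 3 the test called 13524.

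The fixed rule named the 2 transcripts with the largest positive and the 2 with the largest negative fitted log2 change at 14 d. Each had no count in a group compared, where the fitted value is no measured size, so this order is not a ranking by fold. TRINITY_DN48525_c0_g1_i8 had no count in the 3 control libraries, 20.0 ± 2.51 CPM (SD, n = 3) at 7 d and 45.3 ± 25.1 CPM (SD, n = 3) at 14 d, with 16.8 CPM in 14 d replicate 3. Against a bound of 3 counts over the control group it was at least 267-fold higher at 7 d (edgeR quasi-likelihood adjusted p = 0.000434) and at least 604-fold higher at 14 d (edgeR quasi-likelihood adjusted p = 0.000391). It is 1 of 7 tested isoforms of its assembled gene. The sum of that gene rose by less, with log2 changes of 4.97 at 7 d and 5.72 at 14 d (edgeR quasi-likelihood adjusted p = 1.01e-05 and 7.74e-06). TRINITY_DN18978_c0_g1_i25 was also without a count in control leaves. It reached 0.362 CPM at 7 d, with counts in 1 of 3 libraries, and 32.4 ± 27.8 CPM (SD, n = 3) at 14 d, at least 432-fold higher than control (edgeR quasi-likelihood adjusted p = 0.0238). Its level in 14 d replicate 3 was 0.798 CPM, its call was lost without any 1 of the 3 controls or of 14 d replicates 1 and 2, with fitted log2 changes of 11.20 to 11.76 there against 11.75 with all libraries, and its summed assembled gene was not called at 14 d (edgeR quasi-likelihood adjusted p = 0.0631).

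TRINITY_DN6642_c0_g3_i4 was at 91.0 ± 77.7 CPM (SD, n = 3) in control leaves, between 32.5 and 179 CPM, and had no count in any of the 6 salt libraries. It was at least 1188-fold lower at 7 d (edgeR quasi-likelihood adjusted p = 0.00257) and at least 1225-fold lower at 14 d (edgeR quasi-likelihood adjusted p = 0.00415). Control replicate 1 held 2330 of its 3600 control counts, and without it the bounds were 612-fold and 632-fold. TRINITY_DN1688_c0_g1_i10 was at 35.4 ± 29.1 CPM (SD, n = 3) in control leaves, with 1.85 CPM in control replicate 1, at 24.4 ± 1.78 CPM (SD, n = 3) at 7 d, and had no count at 14 d. At 14 d it was at least 476-fold lower than control (edgeR quasi-likelihood adjusted p = 0.00936), whereas the sum of its assembled gene differed from control by a log2 change of -0.37 (edgeR quasi-likelihood adjusted p = 0.0627). With 3 counts per library worth 0.218 to 0.239 CPM, a transcript without counts was below that level and is not shown to be absent. The fold bounds instead set 3 counts over the 3 libraries of a group together, a lower level than 3 counts in each library. They cover counting error only.

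**Figure D4:**
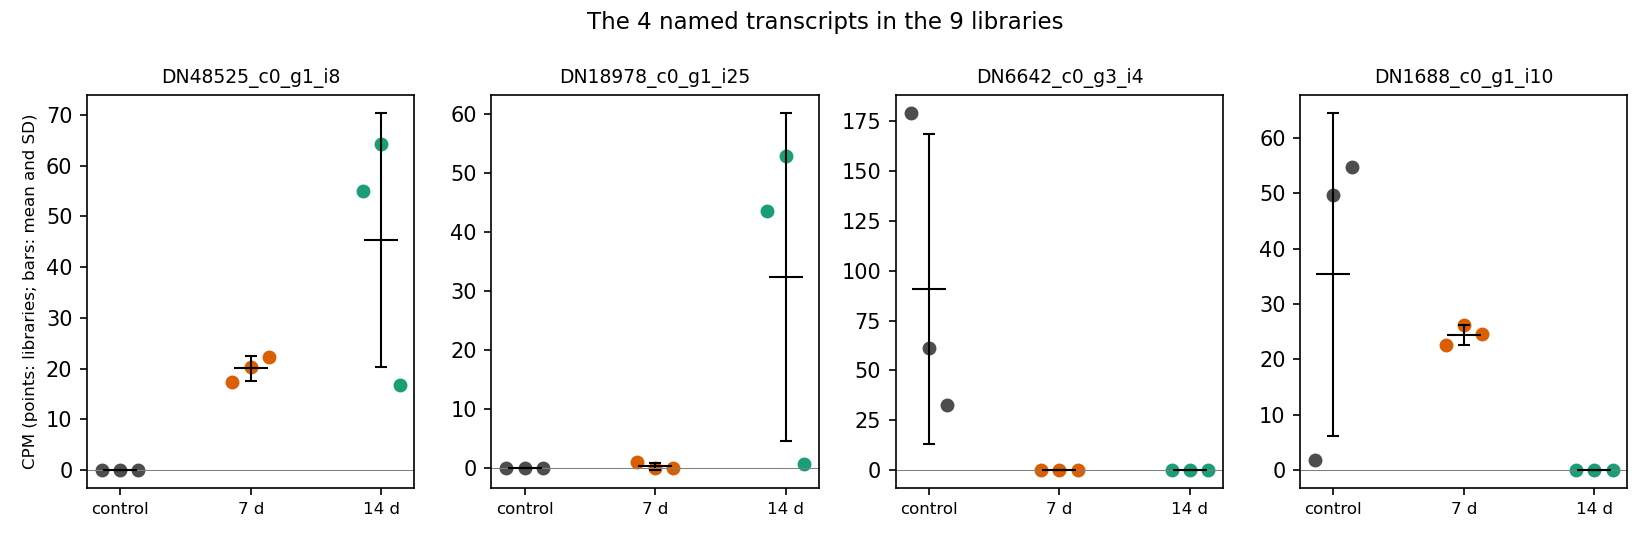
CPM of the 4 transcripts named by the fixed rule, 1 point per library, in control, 7 d and 14 d leaves, with bars for the mean and SD (n = 3) and panel titles without the shared prefix. TRINITY_DN48525_c0_g1_i8 and TRINITY_DN18978_c0_g1_i25 are at 0 in control leaves, TRINITY_DN6642_c0_g3_i4 is at 0 in all salt libraries, and TRINITY_DN1688_c0_g1_i10 is at 0 at 14 d.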

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

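The tests of whether 14 d replicate 3 was a 7 d library, was set apart by depth or a few transcripts, or held RNA of 7 d seedlings were chosen only after that library had been seen to stand apart. The criterion of the last test was also replaced after a first one had been met by no gene. The ratio of squared effects and the thinning were added once the counts of calls were known, before their own values were seen.

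Seedlings at 14 d and at 7 d of salt differed in 6571 transcripts, by the direct test between these times. With 1 control group of unstated sampling day, time in the experiment and duration of salt are not separated. For 114 transcripts both comparisons with the control were called in opposite directions, 34 higher and 80 lower at 7 d. TRINITY_DN1688_c0_g1_i10 differed between the times by a fitted log2 change of -11.34 (edgeR quasi-likelihood adjusted p = 0.0195), a fitted value that is no bound, and was at least 329-fold lower at 14 d than at 7 d. Its call was lost without 7 d replicate 1 (-11.41), 7 d replicate 3 (-11.36), 14 d replicate 1 (-11.35) or 14 d replicate 2 (-11.34), and its assembled gene summed over isoforms was higher at 14 d by 0.43 on the log2 scale (edgeR quasi-likelihood adjusted p = 0.0441).

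Fewer transcripts were called at 14 d than at 7 d against control. Greater spread among the 14 d libraries is argued against as the only cause, since the ratio of squared effects after subtracting the spread was at most 0.747 whichever library was left out. The spread subtracted was an estimate shared by the 3 groups, and the main fit shared its estimate too. Greater spread at 14 d would therefore enter both comparisons with the control there. The median SD of log2 CPM within groups was 0.189 at 7 d, 0.201 at 14 d and 0.223 in control leaves. Fits of only the 2 groups compared called 18365 at 7 d and 8490 at 14 d, a ratio of 0.462, so a part played by spread stays open for such fits. Depth is argued against by the total counts, which were 13166552 to 13962234 in the 7 d libraries and 13373952 to 13723144 in the 14 d libraries. The ratio of calls was 0.579 with all libraries thinned to the lowest total. With totals so alike, thinning could move this ratio little and is no further test. A partial return of leaf transcripts towards the control state between 7 d and 14 d may account for the difference and is a hypothesis. The age or sampling day of the controls stays open, because the labels do not give it.

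14 d replicate 3 stood apart from the other 14 d libraries, at 0.559 of the way from the 7 d to the 14 d group, where the others were at 0.915 and 1.07. Each library was left out of its own group mean. The 14 d end was thus set without replicate 3 for replicate 3 but with it for the others, so these positions are not on 1 scale. The control libraries lay at 0.745 to 0.907 between the full 7 d and 14 d groups, so this axis is not particular to the 14 d state. On the first principal component 14 d replicate 3 was at 19.2 and 14 d replicate 1 at 19.3. It also stood apart on the fourth, which held 7.38% of the variance, at 42.1 against -20.5 to 8.34 in all other libraries. A 7 d library under a 14 d label is argued against, since its highest correlation with a 7 d library was 0.878 and the lowest among 7 d libraries was 0.920. Its share of counts in the 100 most abundant transcripts, 11.2%, and its total count lay within the range of the other 8 libraries. It had the most transcripts with a count, 266239 against at most 261485 in the others. Its share of counts in tested transcripts was the lowest, 96.29% against at least 96.32%. Mixing with RNA of 7 d seedlings stays open: 11 of 22 genes (50%) that were low in 14 d replicates 1 and 2 were lifted by less than 0.5 of the implied share of 0.413, but so were 15 of the 57 genes (26.3%) that set this share, over the 25% that was to count against mixing. A seedling that responded more slowly may also account for it, which was not tested.

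For the pairwise counts, 3 libraries against 3 give 10 splits, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many calls in each comparison: 19334 at 7 d with 1 in the highest other split, 11087 at 14 d with 24, and 6571 between the salt times with 1. For any difference among 3 groups, chance is argued against but not excluded. Of the 280 possible splits, 50 were fitted, the real one and others drawn at random. Only 1 of them, the real one with 20379, gave as many, and the splits outside the draw were not fitted. The highest other split drawn gave 4310 and kept the 3 control libraries together.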

How the results depend on the processing

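The fitted log2 changes of the 4 named transcripts kept their direction wherever they were called, except that TRINITY_DN1688_c0_g1_i10 fell between the salt times while the sum of its gene rose, and counts moved by under 1.5 times except as follows. Testing only transcripts with a mean of 5 CPM or more, which tests fewer, gave 10307 calls at 7 d, 6847 at 14 d, 11327 with any difference, an overlap of 4781 and 3806 sustained. An adjusted p below 0.01 gave 9036, 4476, 1905 between the salt times and 9085 with any difference, with 2765 sustained, 1200 moved back and 381 further changed. Without a filter on low counts, 17816 were called at 14 d, 13520 between the salt times and 32615 with any difference, with 7098 moved back and 3368 further changed, and the cause was not tested. The classes under these last 2 settings were computed only after the data were examined. With each library left out in turn, counts ran from 12227 to 21389 at 7 d, 6342 to 10865 at 14 d, 2352 to 8827 between the salt times, 13524 to 23054 with any difference, 4523 to 6754 in the overlap, 4217 to 5759 sustained, 1518 to 4922 moved back and 541 to 2247 further changed. Leaving out a library also lowers the number of samples. Moves of over 1.5 times came without 7 d replicate 3 (7 d and any difference), without control replicate 3 (7308 at 14 d), without 14 d replicate 1 (14 d, overlap and sustained), and for the calls between salt times and the classes that moved back or changed further without any 1 of the 7 d libraries or 14 d replicates 1 or 2. Without 14 d replicate 3, further changes rose to 2247, also over 1.5 times. Smaller rises there were to 21389 at 7 d, 8827 between the salt times, 23054 with any difference and 4922 moved back. Calls at 14 d, the overlap and sustained transcripts were fewer there, at 10865, 6754 and 5759. The replicate numbers did not pair the samples: the deviations of same-numbered libraries correlated between -0.165 and 0.224, over 0.1 in 1 of 9 pairs, and 2 of 9 libraries correlated best with their own number. With the replicate block the counts were 16216 at 7 d, 8645 at 14 d and 4589 between the salt times. DESeq2 called 18708, 12036 and 8484, and limma-voom 15083, 8996 and 4960. Sums per assembled gene gave 15765, 10237 and 7045 of 62564 genes, and the gene was called in the opposite direction for 207, 89 and 31 called transcripts. The balance of directions moved too: at 14 d 50.2% of calls were higher, but 57.2% with total counts only and 44.6% with limma-voom, and between the salt times 64.7% were higher at 14 d, but 70.9% with total counts only, 57.1% with DESeq2, 57.8% with limma-voom and 58.1% without 14 d replicate 3. For the 4 named transcripts 127 of 142 alternative values stayed on their side of the threshold. The gene lists and their alternatives were not run, since identifiers came without names. In simulation 9 to 12% of 2-fold changes were recovered. Only 100 transcripts were changed at each size there. The adjustment therefore asked for a smaller unadjusted p than in these data, where far more transcripts were called. The share of 2-fold changes recovered in these data may thus differ. What depth, spread and the number of libraries each contribute to this limit was not tested.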

Other observations

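The test of isoforms against their siblings was chosen before its result was seen, and the comparison of the shares that moved back and the counts of transcripts without detection were chosen after the data were examined.

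Some transcripts were detected in each library of a group and had no count in another group. These are isoforms among the 98906 tested, and the sums of their assembled genes were not checked. How many regrouped libraries would give was not computed. At 7 d, 143 transcripts had no count in any salt library and at least 1 CPM in each control library, and 140 showed the converse. At 14 d the numbers were 69 and 53. Between the salt times, 100 transcripts had no count at 7 d and at least 1 CPM in each 14 d library, and 67 showed the converse.

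Transcripts that had fallen at 7 d moved back more often than those that had risen: 27.3% of the former and 12.3% of the latter were in the class that moved back. The share was larger among lower transcripts in 21 of 21 alternatives, by 5.47 points with limma-voom to 19.7 points with a mean of at least 5 CPM. The shares themselves depended on single libraries. They were 17.8% and 5.56% without 14 d replicate 1 and 13.7% and 3.95% without 14 d replicate 2, and the share among higher transcripts was 6.63% without 7 d replicate 1 and 5.09% without 7 d replicate 3. The latter share was also 5.45% at an adjusted p below 0.01, 19.0% with DESeq2, 19.5% with sums per assembled gene and 22.4% without a filter on low counts. These shares were not compared by a test with replicates.

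Some isoforms were called although the sum of their assembled gene was not: 3002 of 19334 at 7 d, 1876 of 11087 at 14 d and 1274 of 6571 between the salt times. For another 207, 89 and 31 the sum was called in the opposite direction. At 7 d, 453 assembled genes had isoforms called in both directions, at 14 d 182 and between the salt times 82. A division of reads among isoforms that varied from seedling to seedling would set an isoform against its siblings within groups. Over 4688 such isoforms with detected siblings, of 4987, the median correlation within groups with the summed siblings was 0.151, against 0.0140 for random pairs of other genes and 0.317 for isoforms whose gene was also called. Random pairs share no variation of a gene and so are too low a standard, and the explanation stays open, as do regulation of single isoforms by salt and a division of reads that differed between groups, each of which may account for these calls.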
